A study of Bos taurus with 18 samples.

How the data were processed

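Bulk poly(A) RNA sequencing was carried out on endometrial cells brushed from the uterus of 6 Holstein cows (Bos taurus). Each cow gave 3 samples: day 4 and day 7 of an untreated synchronized estrous cycle, and day 7 of a second synchronized cycle in which a depot progestin was injected on day 4. Animals A to C received 100 mg of 17-hydroxyprogesterone caproate with 10 mg of progesterone (the 17-OHPC/P4 arm), and animals D to F received 100 mg of progesterone (the P4 arm). The 18 libraries therefore form 6 groups of 3 animals. The animal letter in the labels marks the same cow in all 3 of its samples, so replicates are separate animals within an arm and repeated samples of 1 animal across conditions.

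Per the labels, cells were collected with a cytobrush from the horn on the side of the corpus luteum, kept in RNAlater at -20 °C, and sequenced as 2 x 150 bp paired reads on a DNBSEQ-G400. The submitters' processing notes name cutadapt, FastQC, STAR, featureCounts and DESeq2 without versions. The genome build, the annotation release, the strand setting and how read pairs were counted are not given in the sources used here. The deposited table holds counts per gene as the authors made them, not normalized, for 38001 Ensembl gene identifiers, 17715 of them without a symbol. A further 2007 rows carry a symbol that also stands on another row. Such rows are named by their identifier, and each entered a gene list that holds its symbol. The table held 0 columns of other samples. The reference table at hand matched 0 of its identifiers, so gene names are those of the deposited table, apart from older symbols of a few list members matched through that table, and no coordinates are given.

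Total counts ranged from 29347255 to 40733544 per library, and 21200 to 23297 genes per library had at least 1 count. The 10 largest genes took 6.51% to 15.4% of the counts, mitochondrially encoded genes 4.72% to 12.4%, and genes without a symbol 4.20% to 9.10%. Low counts were mostly even: 79.1% of the counts from 1 to 5 and 77.4% of those from 6 to 20, against 50.8% of those above 1000. Counting both reads of a pair would give such a pattern, and the number of independent fragments would then lie below the count. No 2 of the 153 pairs of libraries were identical, and pairs within a group differed by far more than sampling noise (chi-square per gene 63.3 to 424 over 18 pairs).

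Genes were kept by edgeR's filterByExpr, which left 19638 genes, 4735 of them without a symbol. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors from 0.881 to 1.16, robust dispersion). All 18 libraries were fitted with 1 mean per group, ignoring the pairing by cow. P values were adjusted by Benjamini-Hochberg over all genes tested, and adjusted p under 0.05 was called. Fold changes are given as log2 with their standard error (SE), levels as CPM (counts scaled by library size) with the SD between animals. The biological coefficient of variation was 51.4%, and 39.4% with the animal as a block. The 11 comparisons were day 7 against day 4 of the control cycle (both arms and each arm), treated against control day 7 (both arms and each arm), treated day 7 against control day 4 in each arm, and, between arms, treated day 7, control day 7 and the difference of the treatment responses. A comparison of the day 4 to day 7 change between the arms was added after seeing the data.

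The tests, the alternatives, the rule for naming genes and 31 gene lists (636 symbols, 606 with a row in the table) were chosen before the data were examined. For each comparison, the rule takes the called genes with a symbol that changed in the same direction in every animal (between arms, whose groups do not overlap) and names the 10 higher and the 10 lower with the smallest p, or fewer if fewer pass. Where none passes, it takes the 5 higher and 5 lower symbols with the smallest p, given as values that did not pass. From each list that was called or held called genes it takes up to 4 called members with the largest change. It also takes PGR, ESR1, OXTR, DGAT2, MSTN, SERPINA14, LTF, TINAGL1, CRYGS, SLC2A1, PTGS2, FKBP5, IHH, HAND2, MKI67, FOXJ1, KRT8, S100A8 and PTPRC in every comparison. No row carried the symbol SERPINA14. The text gives the genes of these sets that carry each comparison, and results for some genes are not reported here.

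Lists were tested with camera from limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the 31 lists of a comparison), which asks whether a list stands above or below all other genes. Camera was also run with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it. The lists covered steroid receptors and co-chaperones, early luteal progesterone-responsive genes of ruminant endometrium, progesterone receptor targets, estrogen-responsive genes, proliferation, and markers of ciliated, secretory, general epithelial, stromal, smooth muscle, endothelial, neutrophil, macrophage, T and NK, B, red blood and squamous epithelial cells. They further covered interferon-stimulated, inflammatory, mucosal defence, prostaglandin and oxytocin, immediate early, transporter, fatty acid, cholesterol, steroid metabolism, IGF, WNT with hedgehog and BMP, matrix remodelling, unfolded protein response and mitochondrially encoded genes. Changes of single genes and of list means within animals were tested with exact sign-flip permutation tests, 2-sided, in R. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

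A fit with the animal as a block was also run for every comparison. Deviations from the group means of samples of the same animal had a median r across genes of 0.375 over 18 pairs. They ran from 0.393 to 0.718 in the 17-OHPC/P4 arm and from -0.0712 to 0.357, several of them near 0, in the P4 arm, against -0.144 for different animals of the same arm and -0.002 between arms. Of the variance of log2 CPM, 41.7% lay between groups, 33.7% between animals within an arm and 24.6% in the rest. Between arms, where animals do not overlap, the block was a random effect in limma voom. Other alternatives were DESeq2 1.42.0, limma voom, RLE and upper-quartile factors, no count filter, a filter of CPM of at least 1 in at least 6 libraries, only the compared groups in the fit, the mean of the leukocyte lists as a covariate, glmTreat against a fold of 1.2, and leaving out each library in turn. Leaving out animal C and the tests of list means within animals were added after seeing the data.

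The procedure was tested on simulated counts with the means and library sizes of the 19638 genes and 200 genes changed by known folds, 50 at each fold. At a 4-fold change it recovered 66% of the changed genes for day 7 against day 4 in both arms, 40% in the 17-OHPC/P4 arm and 36% in the P4 arm. At that fold the share was 36%, 50% and 74% for treated against control day 7 (17-OHPC/P4 arm, P4 arm, both arms), 44% and 44% for treated day 7 against control day 4, 40% for treated day 7 between arms, 16% for the response difference and 44% for control day 7 between arms. At a 2-fold change the shares were 22%, 0% and 0%, then 2%, 8% and 36%, then 10% and 4%, then 2%, 4% and 2%, in the same order.

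In every cow the treated cycle came second and only the control cycle was brushed on day 4. Treatment cannot be separated from either, nor control day 7 from that brushing. The arms also differ in progesterone dose and cows. Genes sharing a symbol or near-identical copies, such as the AKR1C family, are uncertain, since the counting could split reads among them.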

Results

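Endometrial gene expression was measured in 6 Holstein cows on day 4 and day 7 of an untreated cycle and on day 7 of a later cycle with a progestin injection on day 4, day 0 being the day of estrus. The early luteal phase is when ovarian progesterone rises after ovulation and the endometrium prepares for an embryo. Animals A to C received 100 mg of 17-hydroxyprogesterone caproate (17-OHPC), a progestin that carries a caproate ester at carbon 17, together with 10 mg of progesterone (P4). Animals D to F received 100 mg of P4. Mean total counts in the 17-OHPC/P4 arm were 34444747 ± 4553236 (SD, n = 3) on day 4, 36056967 ± 3325751 on control day 7 and 36347204 ± 2325519 on treated day 7. The P4 arm had 38031932 ± 2344950, 33024370 ± 3595019 and 34697144 ± 3976237. The design compares each treated cycle with the untreated cycle of the same arm and the treated day 7 samples of both arms with each other.

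**Figure D1:**
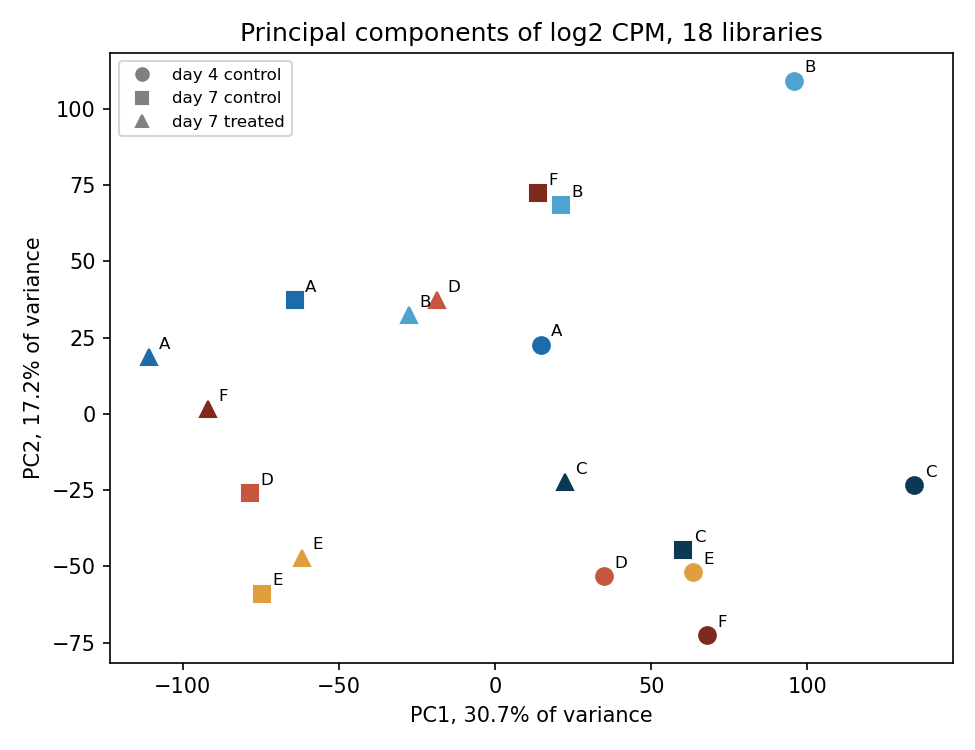
The first 2 principal components of log2 CPM for the 18 libraries, with the percent of variance on each axis (30.7% and 17.2%). Points are libraries, letters and colours are animals, and shapes are the day and cycle. Libraries of animal C lie to the right of those of animal A in each shape.

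The first question was how the endometrium changed between day 4 and day 7 of the untreated cycle. DGAT2 (ENSBTAG00000055742), the enzyme of the last step of triglyceride synthesis, rose from 2.38 ± 1.43 CPM to 386 ± 292 CPM (SD, n = 6), a log2 fold change of 7.32 ± 0.69 (SE, adjusted p = 8.21e-05). LY6G6E (ENSBTAG00000000582), of the LY6 family of surface proteins, rose from 52.1 ± 15.4 to 358 ± 49.8 CPM, by 2.82 ± 0.17 (adjusted p = 1.71e-06). The myosin heavy chain MYH7B rose from 9.97 ± 3.44 to 523 ± 356 CPM, by 5.63 ± 0.48 (adjusted p = 3.39e-05). Further genes higher in 6 of 6 animals were AKAP6, an anchor of protein kinase A (4.45 ± 0.42), the cation channel MCOLN3 (4.90 ± 0.49), the calcium-binding protein SRL (2.67 ± 0.29), SSUH2 (3.09 ± 0.34), DISC1 (3.34 ± 0.38) and the collectin CL46 (6.98 ± 0.62, from 0.0666 CPM). Their adjusted p ran from 4.88e-05 to 0.000421. Genes lower in 6 of 6 animals included the zinc finger gene ZNF84 (-1.13 ± 0.13), the RNA-binding protein MEX3A (-2.56 ± 0.31), the polycomb member CBX2 (-1.85 ± 0.25) and PRAG1 (-1.43 ± 0.21). Also lower were TSR1 (-0.83 ± 0.11), NOP2 (-0.71 ± 0.10) and RRP8 (-0.88 ± 0.13), which act in ribosome assembly. The adjusted p of these lower genes ran from 0.000512 to 0.00179. In all, 1232 genes rose and 841 fell of the 19638 tested, and 1638 of these 2073 changed in the same direction in every animal.

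The receptors of both ovarian steroids were lower on day 7. PGR, the progesterone receptor, fell from 78.9 ± 24.6 to 38.2 ± 10.6 CPM (-1.05 ± 0.26, adjusted p = 0.0209). ESR1, the estrogen receptor alpha, fell from 630 ± 81.4 to 364 ± 121 CPM (-0.79 ± 0.22, adjusted p = 0.032). Both were lower in 6 of 6 animals. GPER1, a membrane receptor for estrogen, rose by 2.52 ± 0.50 (adjusted p = 0.00739). The list of 19 steroid receptors and co-chaperones did not stand apart (adjusted p = 0.932; 2 members rose and 2 fell, or 4 and 3 adjusted over the list alone; median -0.15, mean 0.06). For PGR the call was lost without the day 7 library of animal A (adjusted p = 0.0644), B (0.0552) or E (0.0562). For ESR1 it was lost without the day 7 library of animal A (0.0936), D (0.0721) or E (0.0784), or the day 4 library of animal C (0.0726), D (0.0620), E (0.0627) or F (0.0632).

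Early luteal progesterone-responsive genes stood above the other genes (camera adjusted p = 3.06e-05, adjusted p = 0.195 with an estimated correlation): of 29 members 8 rose and 1 fell, or 12 and 2 adjusted over the list alone. The glutamate transporter SLC1A1 rose by 3.07 ± 0.47 (adjusted p = 0.00221) and the peptidase MEP1B by 4.37 ± 0.64 (adjusted p = 0.00179), each in 6 of 6 animals. TINAGL1, a matrix protein of the same list, had 2.80 ± 0.92 and did not pass (adjusted p = 0.0652, higher in 5 of 6 animals). Of 28 fatty acid and triglyceride genes 8 rose and none fell, or 11 and 0 over the list alone (camera adjusted p = 2.17e-06, adjusted p = 0.267 with an estimated correlation). They included the lipid droplet coat protein PLIN2 (2.28 ± 0.33, adjusted p = 0.00176), the lipase MGLL (2.00 ± 0.38, adjusted p = 0.00629) and the acyl-CoA ligase ACSL3 (1.92 ± 0.41, adjusted p = 0.00996). Steroid metabolism genes were higher (4 of 16 rose, 6 and 1 fell over the list alone, camera adjusted p = 0.00539, adjusted p = 0.144 with an estimated correlation), with HSD17B4 at 1.83 ± 0.35 (adjusted p = 0.00658). Cholesterol biosynthesis genes were too (3 of 23 rose, 3 over the list alone, adjusted p = 0.00539, and 0.843 with an estimated correlation), with MSMO1 at 1.69 ± 0.39 (adjusted p = 0.0151). Among 20 prostaglandin and oxytocin genes 4 rose, 5 over the list alone (adjusted p = 0.0203, adjusted p = 0.195 with an estimated correlation). The prostaglandin F synthase AKR1B1 rose from 260 ± 246 to 1947 ± 1065 CPM (2.90 ± 0.60, adjusted p = 0.00903) and the receptor PTGER4 by 1.93 ± 0.37 (adjusted p = 0.00609). Without animal C's day 4 library the cholesterol call was lost (adjusted p = 0.103).

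Cell division genes stood below the rest: 15 of 30 proliferation genes fell and none rose, or 28 and 0 adjusted over the list alone (camera adjusted p = 1.22e-13, adjusted p = 0.451 with an estimated correlation). MKI67, a marker of dividing cells, fell from 179 ± 158 to 29.5 ± 20.1 CPM (-2.31 ± 0.70, adjusted p = 0.0475). It was lower in 4 of 6 animals, with log2 changes of 0.99 and 0.40 in animals B and C. Its call held without animal B's day 4 or animal C's day 7 library but not without any other of the 12 control libraries (adjusted p from 0.0551 to 0.128). T and NK cell markers were lower in 25 of 25 members (2 fell, 11 over the list alone, camera adjusted p = 1.25e-05, adjusted p = 0.554 with an estimated correlation). Among them the cytokine receptor chain IL2RB had -0.88 ± 0.21 (adjusted p = 0.0174; 0.0551 and 0.0534 without the day 7 library of animal A or B, and 0.0524 without animal F's day 4 library). All 18 immediate early genes had positive values, and 1 rose, also 1 over the list alone (adjusted p = 0.00378, adjusted p = 0.843 with an estimated correlation, 0.115 without animal C's day 7 library).

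The unfolded protein response list (2 of 22 rose, 3 over the list alone) and the 13 mitochondrially encoded genes (0 called, 0 over the list alone) were higher, each at adjusted p = 0.0361. The mean of the first within animals was -0.11 ± 0.190 in the 17-OHPC/P4 arm and 0.73 ± 0.0724 in the P4 arm (SD, n = 3). The adjusted p values were 0.863 and 0.843 with an estimated correlation, and 0.0670 and 0.0672 with the animal as a block. The unfolded protein response call was lost without the day 4 library of animal A (0.147), C (0.0788) or F (0.0660) or the day 7 library of animal B (0.0859). The mitochondrial list was lost without animal B's day 4 library (0.156) or the day 7 library of animal C (0.135), D (0.0539) or E (0.120). Lists of other cell types did not pass: ciliated (adjusted p = 0.36), secretory (0.312), general epithelial (0.932), stromal (0.327), smooth muscle (0.229), endothelial (0.687), neutrophil (0.229), macrophage (0.687), B cell (0.974), red blood cell (0.646) and squamous (0.0737, with KRT14, a basal keratin, higher by 2.58 ± 0.48 at adjusted p = 0.0055). Progesterone receptor targets (0.121), estrogen-responsive genes (0.255), interferon-stimulated genes (0.396), inflammatory genes (0.932), mucosal defence (0.518), transporters (0.229), the IGF axis (0.932), WNT with hedgehog and BMP genes (0.121) and matrix remodelling (0.872) did not pass either. Single members rose within them, such as the transcription factor EPAS1 (2.32 ± 0.41, adjusted p = 0.00422), the insulin receptor INSR (2.00 ± 0.37, adjusted p = 0.00521), the transporter SLC38A7 (1.35 ± 0.24, adjusted p = 0.00437) and the metalloprotease inhibitor TIMP3 (2.53 ± 0.39, adjusted p = 0.00221).

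With the animal as a block 1835 genes rose and 1437 fell on day 7, and DESeq2 called 3478. Leaving out 1 library gave 945 calls without animal A's day 7 library, 996, 1296 and 3192 without that of animal D, E or F, and 1367, 1052 and 1151 without the day 4 library of animal C, E or F.

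**Figure D2:**
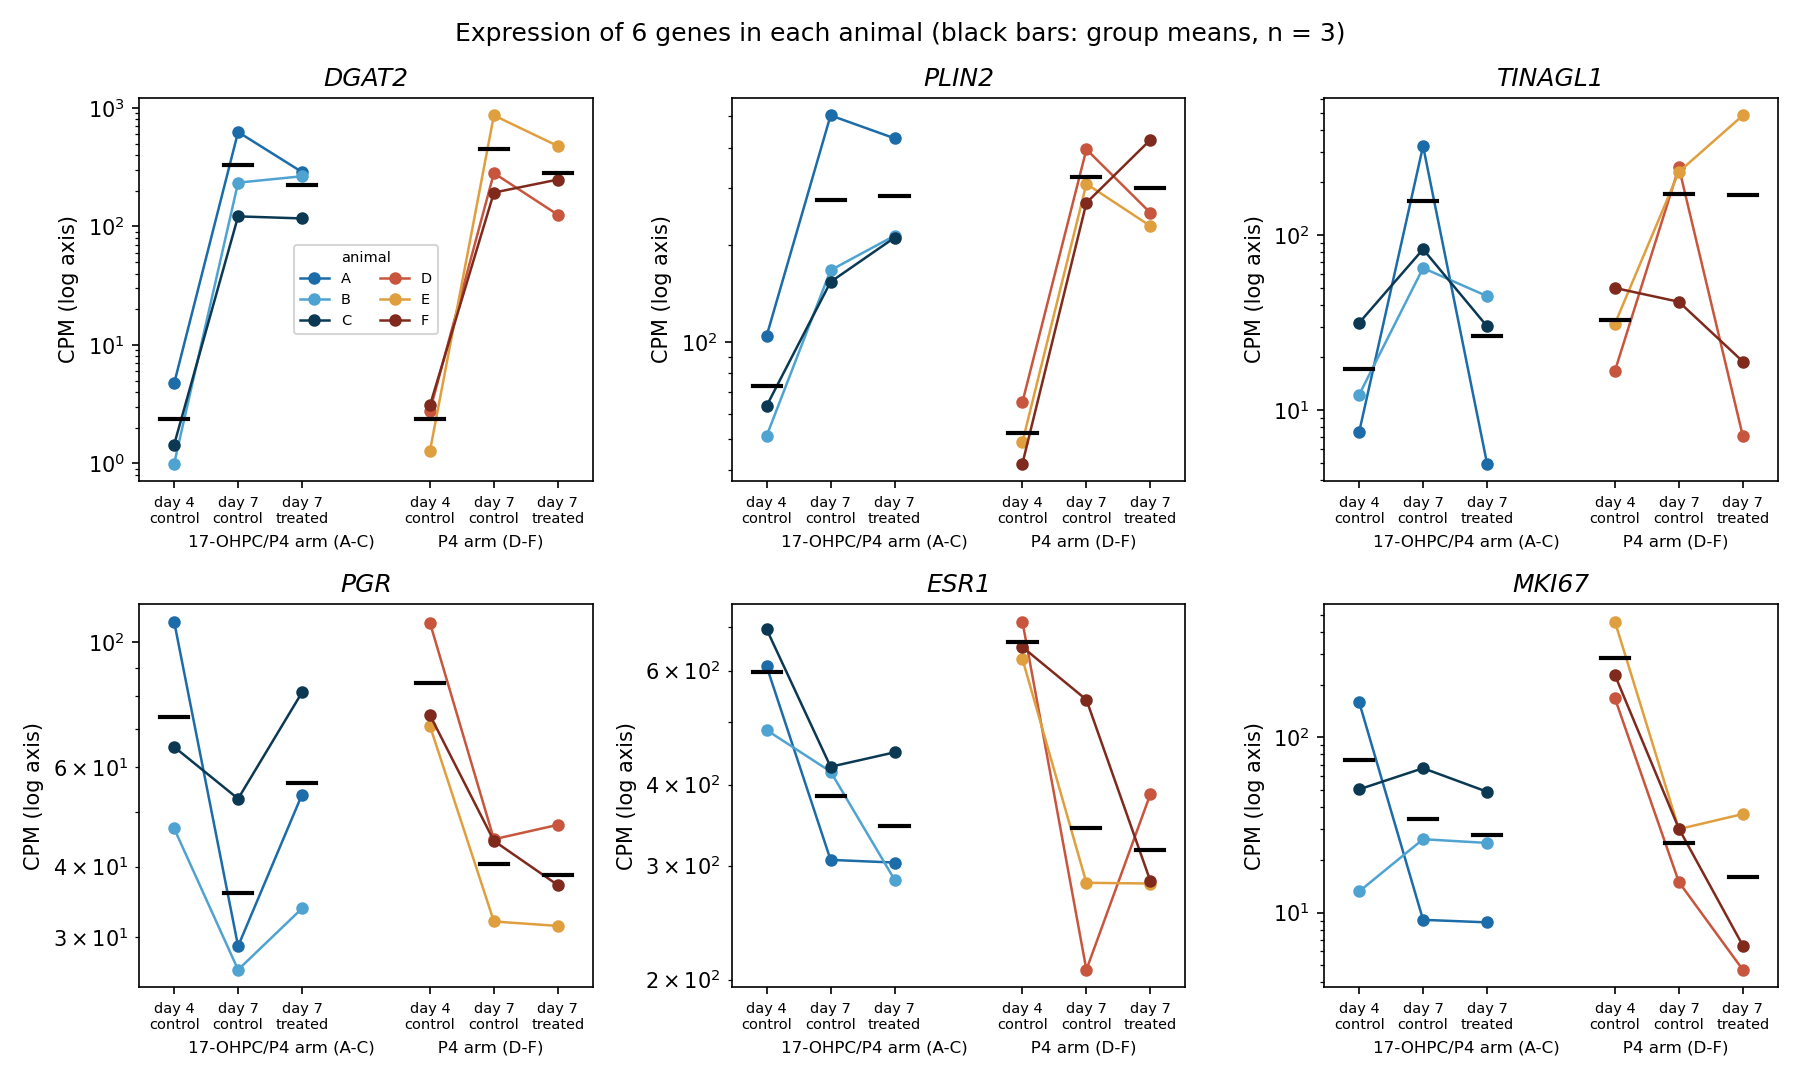
CPM (log axis) of DGAT2, PLIN2, TINAGL1, PGR, ESR1 and MKI67 in each animal on control day 4, control day 7 and treated day 7. Lines join the libraries of 1 animal and black bars are group means (n = 3). DGAT2 rose from a group mean of 2.39 CPM to 327 CPM on control day 7 in animals A to C and from 2.38 to 446 CPM in animals D to F, and MKI67 was higher on control day 7 than on day 4 only in animals B and C.

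Within the 17-OHPC/P4 arm, before treatment, 8 genes rose and none fell between day 4 and day 7 (1890 at unadjusted p under 0.05, limma voom called 3, DESeq2 375, and the animal block 105 higher and 3 lower). LY6G6E rose by 2.46 ± 0.24 (adjusted p = 0.000966), MYH7B by 5.33 ± 0.66 (0.00638), AKAP6 by 4.32 ± 0.59 (0.0112) and DGAT2 by 7.09 ± 0.97, from 2.39 ± 2.04 to 327 ± 264 CPM (adjusted p = 0.0112), each in 3 of 3 animals. CL46 (5.36 ± 0.80) and MCOLN3 (4.64 ± 0.69) were at adjusted p = 0.0204. PGR had -1.03 ± 0.37 (adjusted p = 0.344, lower in 3 of 3 animals) and MKI67 -1.13 ± 0.95 (adjusted p = 0.777, lower in 1 of 3). The count was 1 without the day 4 library of animal B or C and 136 without that of animal A, and it was 5 and 42 without the day 7 library of animal A and C. DGAT2 was at adjusted p = 0.167 and 0.164 without the day 4 library of animal B and C, MYH7B at 0.114 and 0.0735, AKAP6 at 0.167 and 0.0692, CL46 at 0.186 and 0.168 and MCOLN3 at 0.186 and 0.179, while LY6G6E passed without any 1 library. CL46 and MCOLN3 were also lost without animal A's day 7 library (0.0789 and 0.0797), and all 6 in a fit of the compared groups alone (0.407 for LY6G6E and 0.688 for the others).

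Of the lists of this arm 11 were called higher and 2 lower. Steroid metabolism was the only one called with either correlation, as higher (3 of 16 members rose adjusted over the list alone and 0 over all genes, adjusted p = 0.000196, and 0.0218 with an estimated correlation). Early luteal genes (1 of 29 rose, 5 over the list alone, adjusted p = 9.87e-07, adjusted p = 0.109 with an estimated correlation) and fatty acid genes (1 of 28 rose, 2 over the list alone, camera adjusted p = 1.25e-07, adjusted p = 0.166 with an estimated correlation) were higher as well. Prostaglandin genes were higher (0 of 20 called, 3 over the list alone, camera adjusted p = 0.0151, adjusted p = 0.115 with an estimated correlation), a call lost without the day 7 library of animal B (0.0505) or C (0.0996). The immediate early list was higher with 18 of 18 values positive (0 called, 0 over the list alone, camera adjusted p = 0.000246, adjusted p = 0.747 with an estimated correlation, 0.63 without animal C's day 7 library). Proliferation genes were lower in 29 of 30 (0 called, 0 over the list alone, camera adjusted p = 1.03e-07, adjusted p = 0.734 with an estimated correlation, 0.0791 without animal A's day 4 library). Their mean changed by -3.08 in animal A, 0.36 in B and 0.00384 in C. Ciliated cell markers were lower in 21 of 22 (0 called, 0 over the list alone, camera adjusted p = 0.00451, adjusted p = 0.917 with an estimated correlation, 0.894 without animal B's day 4 library and 0.155 without animal C's day 7 library). The interferon list was higher (0 called, camera adjusted p = 0.0251, 0.0575 with the block, adjusted p = 0.917 with an estimated correlation) and turned lower without animal A's day 7 library (0.595). It was also lost without the day 4 library of animal A (0.199) or B (0.269). The last 5 lists had 0 members called over all genes. Cholesterol biosynthesis was higher (median 0.44, camera adjusted p = 0.00127, adjusted p = 0.839 with an estimated correlation, 0.526 without animal C's day 4 library, 0.213 and 0.0767 without the day 7 library of animal A or B). Endothelial markers were higher (median 0.46, camera adjusted p = 0.00857, adjusted p = 0.807 with an estimated correlation, 0.133 and 0.342 without the day 4 library of animal A or B, 0.0951 and 0.111 without the day 7 library of animal B or C). Squamous markers were higher (median 1.11, camera adjusted p = 0.0323, adjusted p = 0.166 with an estimated correlation, 0.0791, 0.234 and 0.0819 without the day 4 library of animal A, B or C, 0.513 and 0.129 without the day 7 library of animal B or C). Progesterone receptor targets were higher (median 0.32, camera adjusted p = 0.0341, adjusted p = 0.233 with an estimated correlation, 0.153 and 0.0561 without the day 4 library of animal B or C, 0.285 without animal C's day 7 library). Transporters were higher (median 0.14, 2 higher over the list alone, camera adjusted p = 0.0381, adjusted p = 0.291 with an estimated correlation, 0.146 without animal A's day 4 library, 0.0729 and 0.0996 without the day 7 library of animal B or C). The endothelial mean changed by 0.28 in animal A, 2.64 in B and 0.00886 in C.

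In the P4 arm 912 genes rose and 786 fell (1535 and 1440 with the animal block). LY6G6E rose by 3.18 ± 0.25 (adjusted p = 4.79e-05), MYH7B by 5.94 ± 0.68 (0.00115) and DGAT2 by 7.55 ± 0.98, from 2.38 ± 0.97 to 446 ± 364 CPM (0.00176). SAT1, the enzyme that acetylates spermidine and spermine, rose from 148 ± 20.4 to 1440 ± 563 CPM (3.28 ± 0.40, adjusted p = 0.00132). MEX3A fell by 4.01 ± 0.48 on the log2 scale (adjusted p = 0.00117), the planar polarity gene VANGL2 by 2.16 ± 0.28 (0.00176) and UTRN, encoding utrophin, by 1.25 ± 0.15 (0.00117), all in 3 of 3 animals. PLIN2 (2.64 ± 0.47, adjusted p = 0.00718) and TIMP3 (3.36 ± 0.57, adjusted p = 0.00599) rose. PGR (-1.06 ± 0.37, adjusted p = 0.0835, and 0.0194 with the block) and ESR1 (-0.95 ± 0.31, adjusted p = 0.0675, and 0.0493 with the block) did not pass without the block. DESeq2 called 3356 genes. The count fell to 271 without animal D's day 7 library, 275 and 349 without the day 4 library of animal E and F, 743 without animal E's day 7 library and 901 without animal D's day 4 library.

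Proliferation genes of the P4 arm were lower in 29 of 30 members (8 fell, 27 over the list alone, adjusted p = 5.78e-13, adjusted p = 0.556 with an estimated correlation). T and NK markers were lower in 25 of 25 (5 fell, 19 over the list alone, camera adjusted p = 3.69e-08, adjusted p = 0.556 with an estimated correlation). The unfolded protein response list was higher in 21 of 22 (3 rose, 10 over the list alone, camera adjusted p = 2.76e-05, adjusted p = 0.556 with an estimated correlation). So were early luteal genes (6 rose and 2 fell of 29, 8 and 3 over the list alone, camera adjusted p = 0.00504, adjusted p = 0.556 with an estimated correlation) and fatty acid genes (6 of 28 rose, 8 and 1 fell over the list alone, camera adjusted p = 0.000526, adjusted p = 0.556 with an estimated correlation). WNT, hedgehog and BMP genes were lower (6 of 32 fell, 8 and 1 rose over the list alone, camera adjusted p = 0.0232, adjusted p = 0.701 with an estimated correlation, 0.114 without animal F's day 7 library). Among them the ligand WNT5A fell from 969 ± 141 to 185 ± 91.8 CPM (-2.39 ± 0.61, adjusted p = 0.0285). The WNT5A call was lost without the day 4 library of animal D (0.0678), E (0.0774) or F (0.0765) or the day 7 library of animal D (0.140) or F (0.0641). Mitochondrial genes were higher (0 of 13 called, 0 over the list alone, camera adjusted p = 0.0386, adjusted p = 0.922 with an estimated correlation, 0.0602 with the block), a call lost without the day 7 library of animal D (0.0592) or E (0.204) or animal D's day 4 library (0.0533). Cholesterol genes passed only with the block (0.0664, and 0.0116 with it, adjusted p = 0.922 with an estimated correlation and no block). Animal F's T and NK list changed by -2.09, against -1.10 and -0.83 in animals D and E, and its ciliated list by 2.38, against -0.94 and -1.71.

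The difference between the arms in this untreated change, tested after seeing the data, passed for 0 genes in edgeR (1514 at unadjusted p under 0.05), and also with the block. The smallest adjusted p was 0.091, for UTRN (difference 1.46 ± 0.21). VANGL2 had 2.34 ± 0.38 (adjusted p = 0.197). Across genes, which are not independent replicates, the log2 changes of both arms had r = 0.495.

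Treatment was set against the untreated cycle to ask what the injection on day 4 did to the day 7 endometrium. No gene passed in edgeR in the 17-OHPC/P4 arm. The genes with the smallest p were the glycolytic enzyme ALDOC (-1.45 ± 0.31, from 11.1 ± 2.69 to 4.05 ± 0.471 CPM, n = 3), the retinol dehydrogenase RDH10 (-1.10 ± 0.31) and the protease TMPRSS4 (-2.15 ± 0.68). Higher values were those of LINS1 (1.11 ± 0.36), AHNAK2 (0.93 ± 0.30) and FKBP9 (1.45 ± 0.47). All were at adjusted p = 0.99. PGR had 0.64 ± 0.37, higher in 3 of 3 animals, DGAT2 -0.55 ± 0.74 and TINAGL1 -2.56 ± 1.29, none of which passed (adjusted p = 0.99). At unadjusted p under 0.05 there were 371 genes with edgeR, 850 with the block, 374 with limma voom and 671 with DESeq2. After adjustment the block and limma voom called 0 and DESeq2 1, ALDOC (-1.43, adjusted p = 0.0477). For a median gene the 95% interval reached 0.923 log2 to either side, and for 39.7% of genes it lay within 1 log2.

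In the P4 arm no gene passed in edgeR either. NR1I3, a nuclear receptor of drug and steroid metabolism, had 2.74 ± 0.48, from 0.15 ± 0.0158 to 1.02 ± 0.3 CPM (SD, n = 3, adjusted p = 0.889). The galectin LGALS3 had -1.28 ± 0.31, from 181 ± 5.69 to 74.9 ± 23.1 CPM, the immunoglobulin A receptor FCAR -4.47 ± 1.16, OSTF1 -0.60 ± 0.13, NEK8 0.65 ± 0.16 and ALDOC -1.09 ± 0.31. These last 5 were at adjusted p = 1, and all 6 moved in the same direction in 3 of 3 animals. PGR had -0.06 ± 0.36 and DGAT2 -0.65 ± 0.74. At unadjusted p under 0.05 there were 596 genes with edgeR, 881 with the block, 478 with limma voom and 933 with DESeq2. After adjustment the block and limma voom called 0, and DESeq2 called 2, OSTF1 (-0.61) and NR1I3 (2.76), both at adjusted p = 0.00801. The interval lay within 1 log2 for 41.3% of genes.

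Over both arms, ALDOC was lower in 6 of 6 animals, by -0.55 to -1.58 (log2 -1.27 ± 0.22, from 10.7 ± 2.49 to 4.46 ± 0.76 CPM, n = 6), at adjusted p = 0.702 in edgeR and 5.25e-05 in DESeq2. C5AR1, the complement C5a receptor of myeloid cells, was lower in 6 of 6 animals (-1.79 ± 0.42, from 44.6 ± 28.4 to 12.3 ± 10.9 CPM, adjusted p = 0.896), as were MAPKAPK3 (-0.54 ± 0.13) and OSTF1 (-0.40 ± 0.09). KMT2A (0.55 ± 0.17), ACTR3B (0.63 ± 0.19) and SIDT2 (0.78 ± 0.24) were higher in 6 of 6. No gene passed in edgeR (850 at unadjusted p under 0.05, 1316 with the block, 766 with limma voom, 1257 with DESeq2). The block and limma voom called 0 and DESeq2 called 2, ALDOC and OSTF1 (-0.40, adjusted p = 0.0475). The progesterone receptor PGR had 0.29 ± 0.26 (adjusted p = 0.897), ESR1 -0.13 ± 0.22 (0.935), the glucocorticoid and progestin target FKBP5 0.41 ± 0.33 (0.896), DGAT2 -0.60 ± 0.52 (0.897) and the neutrophil gene S100A8 -1.92 ± 1.12 (0.896). The interval lay within 1 log2 for 54.1% of genes.

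Macrophage, neutrophil, interferon, inflammatory and mucosal defence lists were lower in the treated cycle over both arms. T and NK markers (median 0.02, adjusted p = 0.664) and B cell markers (median -0.34, adjusted p = 0.885, the test pointing up) were not called. Macrophage and dendritic cell markers had a median log2 change of -1.08, negative in 15 of 16 members (camera adjusted p = 9.72e-09, adjusted p = 0.277 with an estimated correlation). Interferon-stimulated genes had -0.52, negative in 25 of 27 (camera adjusted p = 5.92e-09, adjusted p = 0.277 with an estimated correlation), and inflammatory genes -0.81, negative in 17 of 21 (camera adjusted p = 1.52e-05, adjusted p = 0.277 with an estimated correlation). Neutrophil markers (median -1.20, camera adjusted p = 3.51e-05, adjusted p = 0.427 with an estimated correlation) and mucosal defence genes (median -0.74, camera adjusted p = 0.00106, adjusted p = 0.285 with an estimated correlation) were lower as well. So were early luteal genes (median -0.42, camera adjusted p = 3.51e-05, adjusted p = 0.173 with an estimated correlation), steroid metabolism (median -0.40, camera adjusted p = 0.00369, adjusted p = 0.142 with an estimated correlation) and squamous markers (median -0.75, camera adjusted p = 0.0384, adjusted p = 0.221 with an estimated correlation). These 8 calls held without any 1 library. Not so the others. Proliferation genes were lower (median -0.55, camera adjusted p = 7.43e-05, adjusted p = 0.742 with an estimated correlation, 0.0549 without animal C's control day 7 library). Secretory markers were lower (median -0.77, camera adjusted p = 0.00202, adjusted p = 0.277 with an estimated correlation, 0.0908 without animal F's control library), and so was matrix remodelling (median -0.48, camera adjusted p = 0.000405, adjusted p = 0.717 with an estimated correlation, 0.532 without animal C's control library). Mitochondrial genes were higher (median 0.20, camera adjusted p = 0.00442, adjusted p = 0.717 with an estimated correlation, 0.297 without animal D's treated and 0.228 without animal F's control library). Prostaglandin genes were lower (median -0.20, camera adjusted p = 0.0384, adjusted p = 0.221 with an estimated correlation), a call lost without the treated library of animal A (0.0793) or D (0.214) or the control library of animal C (0.0764), D (0.132) or E (0.110). No member of any list was called, over all genes or adjusted over the list alone. Fry called 1 of the 31 lists in this comparison (adjusted p = 0.017). With the block the smooth muscle list was also called, as higher (0.0574, and 0.0182 with it, adjusted p = 0.791 with an estimated correlation and no block). Lists were also averaged within animals and tested by exact permutation over 64 sign assignments: early luteal, squamous, inflammatory, steroid metabolism and matrix genes were lower in 6 of 6 animals (p = 0.0312, the smallest possible, and 0.194 adjusted over the 31 lists). The macrophage mean was -0.88 ± 1.05 in the 17-OHPC/P4 arm and -1.13 ± 0.309 in the P4 arm (SD, n = 3) and negative in 5 of 6 animals (exact p = 0.0625, and 0.242 adjusted over the lists).

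**Figure D3:**
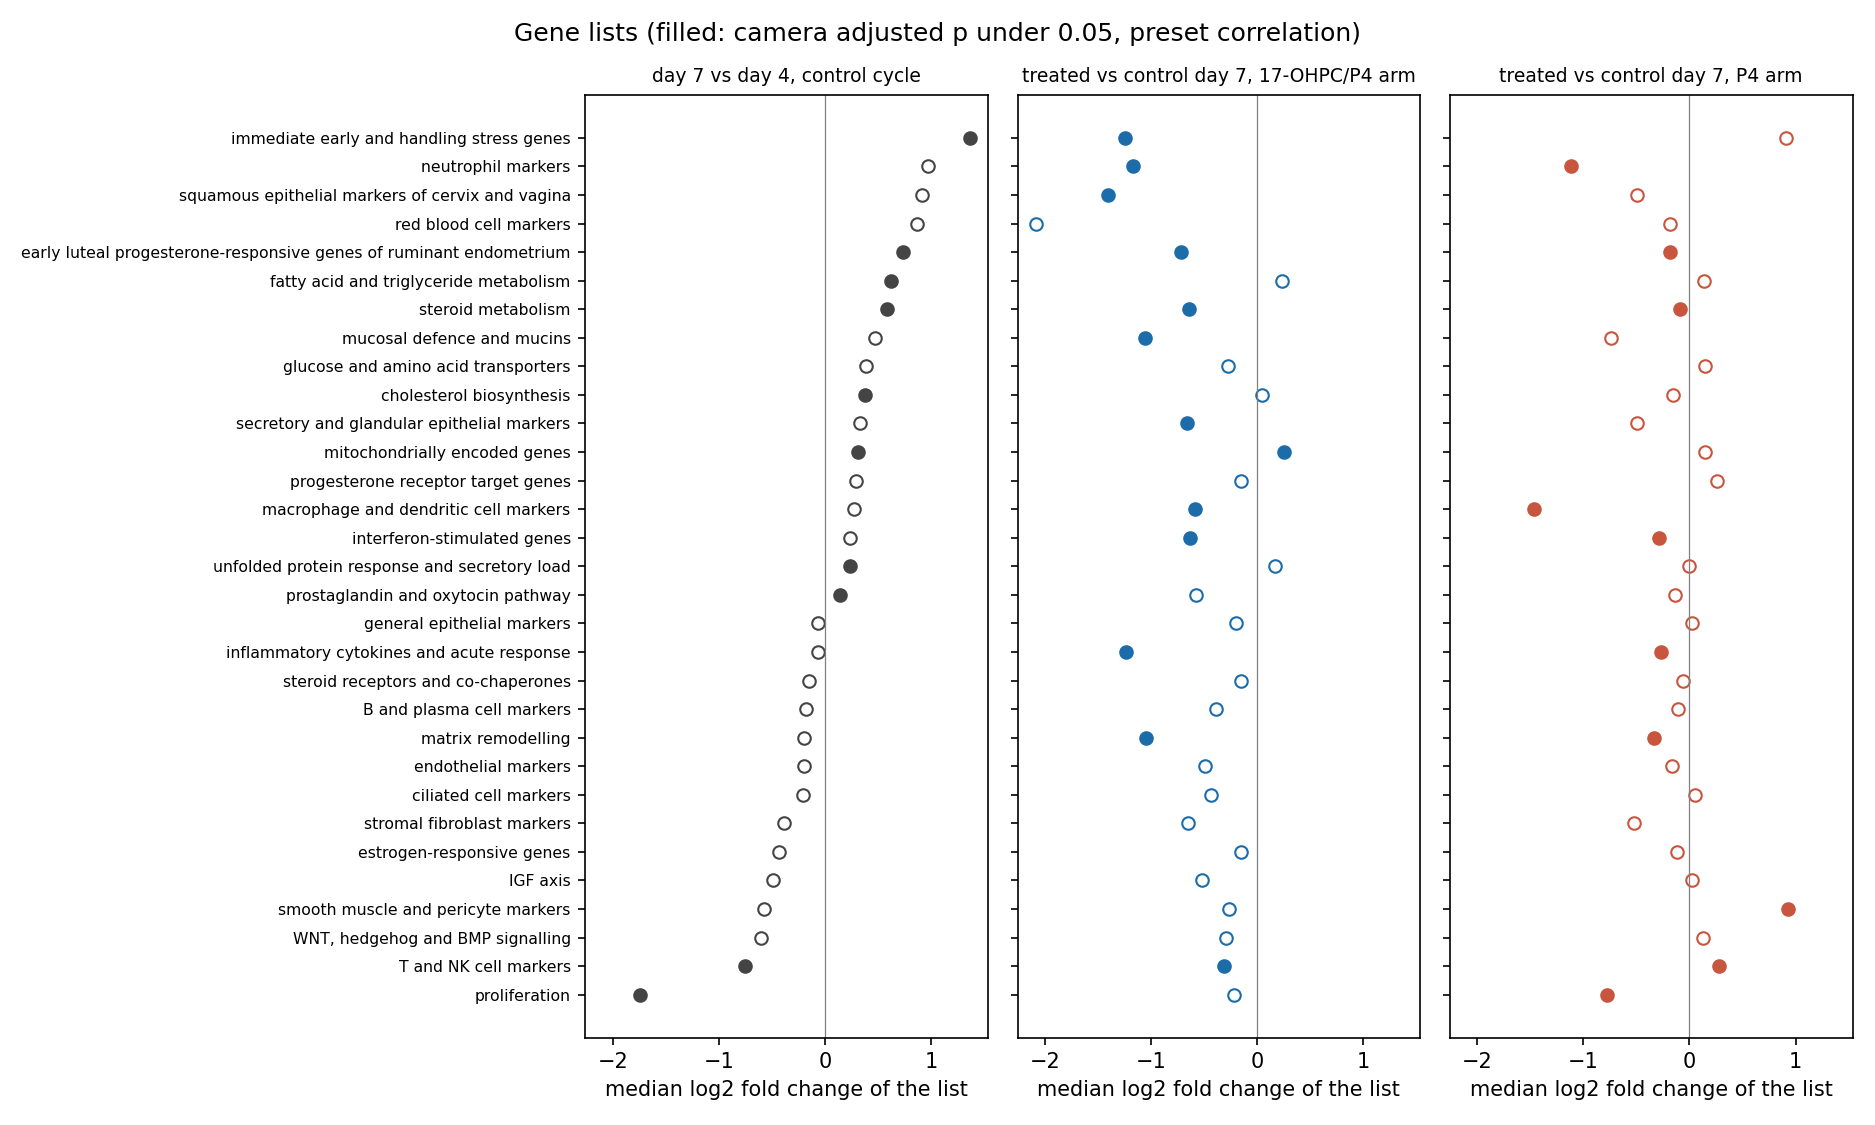
Median log2 fold change of the members of each gene list for day 7 against day 4 of the control cycle (both arms) and for treated against control day 7 in each arm. Each point is 1 list, filled where camera with the preset correlation gave an adjusted p under 0.05, and the macrophage list lies at -0.58 in the 17-OHPC/P4 arm and -1.46 in the P4 arm.

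Within the 17-OHPC/P4 arm the macrophage list had a median of -0.58 with 16 of 16 negative (adjusted p = 0.00138, adjusted p = 0.721 with an estimated correlation), a call lost without animal A's treated (0.588) or animal C's control library (0.463). The interferon list had -0.63 (camera adjusted p = 6.91e-08, adjusted p = 0.378 with an estimated correlation, 0.181 without animal A's control library) and the inflammatory list -1.24 (camera adjusted p = 0.000123, adjusted p = 0.378 with an estimated correlation, 0.231 without animal C's control library). In all 13 lists were called in this arm. None held with an estimated correlation (smallest adjusted p = 0.332), fry called none of them, and each was lost without at least 1 of the 6 libraries. Early luteal genes were lower (median -0.72, camera adjusted p = 0.000663, adjusted p = 0.332 with an estimated correlation, 0.0696 without animal A's control library). Secretory markers were lower (median -0.66, camera adjusted p = 0.00621, adjusted p = 0.378 with an estimated correlation, 0.0946 and 0.129 without animal C's control or animal A's treated library). Neutrophil markers were lower (median -1.17, camera adjusted p = 0.00102, adjusted p = 0.706 with an estimated correlation, 0.367 without animal A's treated library). Squamous markers were lower (median -1.41, camera adjusted p = 0.047, adjusted p = 0.339 with an estimated correlation, 0.0648 and 0.0525 without animal B's control or animal B's treated library). Mucosal defence was lower (median -1.06, camera adjusted p = 0.00285, adjusted p = 0.378 with an estimated correlation, 0.103 and 0.117 without animal C's control or animal A's treated library). Steroid metabolism was lower (median -0.64, camera adjusted p = 0.0298, adjusted p = 0.332 with an estimated correlation, 0.106 without animal A's control library, 0.0525 and 0.0752 without the treated library of animal B or C). Immediate early genes were lower (median -1.25, camera adjusted p = 0.00375, adjusted p = 0.721 with an estimated correlation, 0.231 and turned without animal C's control library, 0.103 and 0.128 without the treated library of animal A or C). Matrix remodelling was lower (median -1.05, camera adjusted p = 0.00575, adjusted p = 0.721 with an estimated correlation, 0.231 and turned without animal C's control library, 0.243 and 0.0941 without the treated library of animal A or B). Mitochondrial genes were higher (median 0.25, camera adjusted p = 0.00575, adjusted p = 0.721 with an estimated correlation, 0.0509 and 0.0524 without the control library of animal A or B, 0.174 without animal B's treated library).

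In the P4 arm the macrophage list had a median of -1.46 with 15 of 16 negative (camera adjusted p = 1.11e-08, adjusted p = 0.612 with an estimated correlation) and proliferation -0.78 with 28 of 30 negative (camera adjusted p = 1.1e-09, adjusted p = 0.612 with an estimated correlation), and both held without any 1 library. These were 2 of 10 lists called in the P4 arm, none of which held with an estimated correlation (smallest adjusted p = 0.481) or was called by fry. The other 8 were each lost without at least 1 library. Interferon-stimulated genes were lower (median -0.29, camera adjusted p = 0.000355, adjusted p = 0.612 with an estimated correlation, 0.398 and 0.069 without animal E's control or animal F's treated library). Inflammatory genes were lower (median -0.27, camera adjusted p = 0.00667, adjusted p = 0.612 with an estimated correlation, 0.0805 and 0.159 without animal E's control or animal F's treated library). Neutrophil markers were lower (median -1.12, camera adjusted p = 0.00462, adjusted p = 0.612 with an estimated correlation, 0.067 and 0.287 without the control library of animal D or E, 0.0594 without animal F's treated library). Early luteal genes were lower (median -0.18, camera adjusted p = 0.00664, adjusted p = 0.612 with an estimated correlation, 0.0654 and 0.198 without the control library of animal D or E, 0.419 without animal D's treated library). Steroid metabolism was lower (median -0.09, camera adjusted p = 0.0267, adjusted p = 0.481 with an estimated correlation, 0.0741 and 0.149 without the control library of animal D or E, 0.222 and 0.108 without the treated library of animal D or F). Matrix remodelling was lower (median -0.33, camera adjusted p = 0.012, adjusted p = 0.761 with an estimated correlation, 0.067 and 0.258 without the control library of animal D or E, 0.195 and 0.12 without the treated library of animal D or F). Smooth muscle markers were higher (median 0.93, camera adjusted p = 0.012, adjusted p = 0.612 with an estimated correlation, 0.777 and 0.577 without animal F's control or animal D's treated library). The proliferation mean was -0.83 in animal D, 0.27 in E and -2.27 in F. T and NK markers went up in the P4 arm (median 0.28, camera adjusted p = 0.00658, adjusted p = 0.612 with an estimated correlation, 0.123 without animal D's control library). In the other arm they went down (median -0.31, camera adjusted p = 0.0465, 0.0503 with the block, adjusted p = 0.721 with an estimated correlation, 0.61, 0.22 and 0.356 without animal A's treated, animal B's control or animal C's control library). The difference between the arms is given with the other tests between arms. No list member was called in either arm, over all genes or over the list alone. Libraries that stood apart were animal A's treated library, with S100A8 at 0 CPM against 7.74 CPM in its control library, and animal C's control day 7 library, with the immediate early list -2.99 lower in the treated than in the control library. In animal F's control day 7 library ciliated markers lay at 1.44 log2 from the mean of all libraries, against -1.28 and -2.09 in animals D and E, and stromal markers at -2.21, against 0.74 and 0.18. In animal E's treated library the immediate early list lay at 2.35, against -0.25 and -0.76 in those of animals D and F. Animal D's treated library had the mitochondrial list at 0.85, against 0.45 and -0.09, and of the 18 libraries the highest shares of counts in mitochondrial genes and in the 10 largest genes.

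The responses of the arms, as log2 changes over 19638 genes, had r = 0.319 across genes. Genes are not independent replicates, and an exact permutation over 64 sign assignments of the animals gave p = 0.3125 (the smallest possible was 0.0625). Without animal F the value was -0.108, and without any other 1 animal it lay from 0.257 to 0.457. The 200 genes that rose most clearly from day 4 to day 7 in the P4 arm had a median treatment response of 0.33 in the 17-OHPC/P4 arm, positive for 84%, which fry did not call. Unadjusted fry p was 0.0268 with the block (median 0.46) and 0.0475 without animal C's treated library (0.53). Without animal A's treated or control library the median was 0.12 or 0.62. The 200 genes that fell most clearly had a median of -0.13 and were not called (0.03 without animal C's control library). In the P4 arm, the genes chosen in the 17-OHPC/P4 arm had medians of 0.02 and -0.09 and were not called, the first with fry pointing down against the sign of the median. Without animal F's control library these were -0.25 and 0.04, and the first was -0.25 without animal F's and -0.02 without animal E's treated library.

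**Figure D4:**
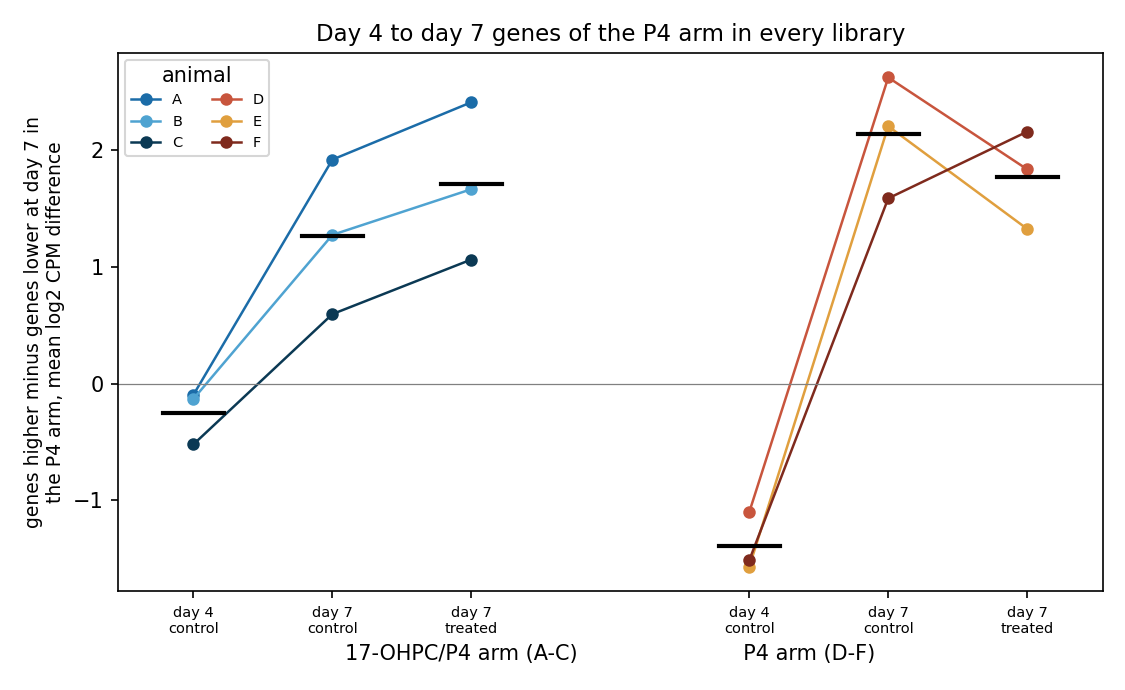
Score of each library on the 912 genes higher and 786 genes lower on day 7 in the P4 arm (mean log2 CPM difference). Points are libraries, lines join animals and bars are group means, and the 17-OHPC/P4 arm went from -0.249 on day 4 to 1.26 on control and 1.71 on treated day 7, and the P4 arm, in which the genes were chosen, from -1.39 to 2.14 and 1.77.

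Treated day 7 was also compared with control day 4, the day of injection in the cycle before. In the 17-OHPC/P4 arm 129 genes rose and 5 fell (832 and 197 with the block). LY6G6E rose by 2.22 ± 0.24 (adjusted p = 0.00162), MYH7B by 5.99 ± 0.68, from 8.35 ± 4.54 to 529 ± 224 CPM (0.00224), DGAT2 by 6.54 ± 0.94 (0.0154) and HLA-DOB, of antigen presentation, by 3.35 ± 0.49 (0.0158), in 3 of 3 animals. All 5 lower genes are named by the rule: RPL7A (-1.07 ± 0.19, adjusted p = 0.0268), TRMT1 (-0.77), FBL (-0.88 ± 0.17), IFRD2 (-0.80) and TSR1 (-0.76 ± 0.16), of which RPL7A, FBL and TSR1 serve the ribosome and TRMT1 modifies transfer RNA. PGR had -0.39 ± 0.36 (adjusted p = 0.54). The count was 3 and 4 without the day 4 library of animal B and C, 1018 without that of animal A, 5, 35 and 231 without the treated library of animal A, B and C, and 0 in a fit of the compared groups alone, while DESeq2 called 1448. DGAT2 was at adjusted p = 0.0928 and 0.105 without the day 4 library of animal B and C and 0.0510 without animal A's treated library, and HLA-DOB at 0.0912, 0.0741 and 0.0637. The 5 lower genes were at 0.105 to 0.208 without animal C's and 0.110 to 0.177 without animal B's day 4 library. Those 5 were also lost without the treated library of animal A (0.144 to 0.221) or B (0.0694 to 0.109), and FBL and IFRD2 without that of animal C (0.0540 and 0.0522). LY6G6E and MYH7B held without any 1 library.

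Fatty acid genes were higher in this comparison (1 of 28 rose, 9 and 1 fell over the list alone, adjusted p = 1.49e-06, adjusted p = 0.905 with an estimated correlation), a call that held without any 1 library. Proliferation genes were lower in 29 of 30 (0 called, 0 over the list alone, camera adjusted p = 4.75e-05, adjusted p = 0.905 with an estimated correlation, 0.188 without animal A's day 4 library). Ciliated markers were lower in 20 of 22 (0 called, 0 over the list alone, camera adjusted p = 0.00507, adjusted p = 0.905 with an estimated correlation, 0.100 and 0.244 without animal A's treated and animal B's day 4 library). The remaining 3 calls had 0 called members, over all genes or over the list alone. T and NK markers were lower (median -0.64, camera adjusted p = 0.0426, adjusted p = 0.905 with an estimated correlation, 0.132 and 0.275 without the day 4 library of animal B or C, 0.147 without animal A's treated library). Cholesterol biosynthesis was higher (median 0.56, camera adjusted p = 0.018, adjusted p = 0.905 with an estimated correlation, 0.634 and 0.191 without animal C's day 4 or animal B's treated library). Mitochondrial genes were higher (median 0.58, camera adjusted p = 0.0171, adjusted p = 0.905 with an estimated correlation, 0.132 and 0.0808 without animal B's day 4 or animal B's treated library). The early luteal list was not called (2 of 29 rose, 4 over the list alone; adjusted p = 0.168; median -0.37, mean 0.37, test pointing up).

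The P4 arm had 848 genes that rose and 620 that fell (1525 and 1177 with the block). LY6G6E rose by 3.02 ± 0.25 (adjusted p = 8.9e-05), SAT1 from 148 ± 20.4 to 1467 ± 111 CPM (3.30 ± 0.40, 0.00236), the autophagy genes WIPI1 by 2.94 ± 0.39 and MAP1LC3A by 4.10 ± 0.54 (both 0.00301), and DGAT2 by 6.90 ± 0.96 (0.0036). Genes that fell included the replication licensing factor MCM3 (-2.01 ± 0.32, adjusted p = 0.0067), the tubulin regulator STMN1 (-2.48 ± 0.39, adjusted p = 0.00634) and MKI67, from 284 ± 154 to 15.9 ± 17.9 CPM (-4.16 ± 1.07, adjusted p = 0.0331). Of 30 proliferation genes 26 fell and none rose, 28 over the list alone (camera adjusted p = 1.49e-23, adjusted p = 0.909 with an estimated correlation). MEX3A fell by 3.06 ± 0.45 on the log2 scale (0.00464), and PGR had -1.13 ± 0.37 (0.0757, and 0.0166 with the block). Unfolded protein response genes (3 of 22 rose, 5 over the list alone, camera adjusted p = 0.000174, adjusted p = 0.909 with an estimated correlation) and fatty acid genes (7 of 28 rose, 11 and 1 fell over the list alone, camera adjusted p = 0.000167, adjusted p = 0.909 with an estimated correlation) were higher. T and NK markers were lower in 25 of 25 (0 called, 0 over the list alone, camera adjusted p = 5.31e-05, adjusted p = 0.909 with an estimated correlation). Immediate early genes (2 rose, 3 over the list alone) and mitochondrial genes (1 rose, 5 over the list alone) were higher. Their camera adjusted p were 0.012 (0.531 without animal E's treated library) and 0.00201 (0.0587 without animal D's treated library), and each had an adjusted p = 0.909 with an estimated correlation. Only with the block were stromal (0.108, and 0.0051 with it), macrophage (0.0515, and 0.00666), WNT (0.0718, and 0.0155) and matrix (0.098, and 0.00322) lists called, as lower. Without the block each had an adjusted p = 0.909 with an estimated correlation. The count of genes was 56 and 94 without the day 4 library of animal E and F, 799 without that of animal D, and 138 and 707 without the treated library of animal F and D; DESeq2 called 2915. MKI67 was lost without the day 4 library of animal E (0.117) or F (0.0813) or the treated library of animal D (0.0915) or F (0.145).

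The compounds were compared on treated day 7. Their doses differ: 100 mg of 17-OHPC with 10 mg of P4 against 100 mg of P4, so the values stand side by side and do not compare equal doses. No gene with a symbol passed. ENSBTAG00000071406 was lower in the 17-OHPC/P4 arm by -3.30 ± 0.36 (adjusted p = 0.00381) and ENSBTAG00000072338 by -1.46 ± 0.18 (adjusted p = 0.00831), the 2 genes called of 19638; they carry no symbol and were named after their values were seen. On control day 7, before any treatment, the first differed by -2.99 ± 0.36 (adjusted p = 0.011) and the second by -0.86 ± 0.18 (adjusted p = 0.132). The response differences were -0.31 (95% interval -1.31 to 0.69) and -0.61 (-1.14 to -0.07, adjusted p = 1). ENSBTAG00000071406 lay from 35.7 to 118 CPM in the libraries of animals A to C and from 431 to 835 CPM in those of D to F. The symbols with the smallest p were ZMAT2 (0.81 ± 0.14), GABARAP, of autophagosome formation (1.05 ± 0.20, adjusted p = 0.139), NEK8 (-0.94 ± 0.16) and the T cell costimulator TNFRSF4 (-2.06 ± 0.37, adjusted p = 0.11), with 0.0934 for ZMAT2 and NEK8. PGR differed by 0.54 (95% interval -0.24 to 1.32), DGAT2 by -0.35 (-1.92 to 1.23), ESR1 by 0.12 (-0.53 to 0.78) and TINAGL1 by -2.67 (-5.43 to 0.09). The interval lay within 1 log2 for 36.2% of genes. DESeq2 called 91 higher and 88 lower, and edgeR called 0 without the treated library of animal A or B and 1 without that of animal C or E. Proliferation genes were higher in the 17-OHPC/P4 arm (27 of 30 positive, camera adjusted p = 5.22e-06, adjusted p = 0.997 with an estimated correlation). Unfolded protein response genes were lower (camera adjusted p = 0.0116, adjusted p = 0.997 with an estimated correlation, 0.563 without animal C's and 0.78 without animal F's treated library). So were mitochondrial genes (camera adjusted p = 0.0409, adjusted p = 0.997 with an estimated correlation, 0.0931, 0.191, 0.651 and 0.0741 without the treated library of animal A, C, D or E). No member of these lists was called, over all genes or adjusted over the list alone.

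The difference of the treatment responses takes each arm against its own control cycle. No gene passed in edgeR (247 at unadjusted p under 0.05, 492 with the block, 217 with limma voom, 470 with DESeq2), and the block, limma voom and DESeq2 called 0. NR1I3 had the lowest p of the named genes (-3.07 ± 0.65, 95% interval -4.46 to -1.68, adjusted p = 1), ahead of the immediate early receptor NR4A2 (-2.69 ± 0.84), OSTC (0.99 ± 0.35) and HSD17B1 (2.00 ± 0.73). PGR differed by 0.71 (-0.39 to 1.81) and DGAT2 by 0.10 (-2.12 to 2.32). For a median gene the interval reached 1.30 log2 to either side, and it lay within 1 log2 for 26.1%. T and NK markers were lower in the response of the 17-OHPC/P4 arm (22 of 25 negative, camera adjusted p = 6.21e-05, adjusted p = 0.878 with an estimated correlation), and this held without any 1 library. Proliferation genes were higher (camera adjusted p = 8.82e-06, adjusted p = 0.878 with an estimated correlation, 0.0781 and 0.116 without the control library of animal A or F) and immediate early genes lower (camera adjusted p = 8.8e-05, adjusted p = 0.878 with an estimated correlation, 0.864 without animal C's control and 0.456 without animal E's treated library). No member of these lists was called, over all genes or over the list alone.

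The arms were also compared on control day 7, before any treatment, to show how far their animals differed. Only ENSBTAG00000071406 passed. Among symbols, the zinc transporter SLC39A5 (-1.82 ± 0.30, adjusted p = 0.0695), EEF1D (-2.26 ± 0.40, adjusted p = 0.073), MDM2, which targets p53 (0.70 ± 0.14, adjusted p = 0.125), and ZMAT2 (0.66 ± 0.14, adjusted p = 0.143) did not pass, though their groups did not overlap. Chance alone gives that in 10% of genes for 3 against 3. Unfolded protein response genes were lower in the 17-OHPC/P4 arm (20 of 22 negative, 0 called and 2 over the list alone, camera adjusted p = 1.04e-06, adjusted p = 0.899 with an estimated correlation). T and NK markers were higher (22 of 25 positive, 0 called, 0 over the list alone, camera adjusted p = 0.001, adjusted p = 0.899 with an estimated correlation). Both held without any 1 library. The other 4 calls did not, and none of their members passed over all genes. Ciliated markers were higher (median 0.48, camera adjusted p = 0.0357, adjusted p = 0.899 with an estimated correlation, 0.825, 0.228 and 0.897 without the control library of animal B, D or E). Immediate early genes were higher (median 1.07, camera adjusted p = 0.0106, adjusted p = 0.899 with an estimated correlation, 0.837 and turned without animal C's control library). Cholesterol biosynthesis was lower (median -0.38, camera adjusted p = 0.00842, adjusted p = 0.899 with an estimated correlation, 0.936 and turned without animal C's control library). Mitochondrial genes were lower (median -0.31, 1 lower over the list alone, camera adjusted p = 0.00392, adjusted p = 0.899 with an estimated correlation, 0.0817 without animal E's control library). DESeq2 called 117 higher and 219 lower. EdgeR called 0 without the control day 7 library of animal A, B or C and 264 without that of animal F.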

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

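All tests of explanations in this part, the comparison of the day 4 to day 7 change between the arms, the splits within animals and the averages of lists within animals were chosen after the results were seen.

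Between the arms, 5 gene lists differed in the treatment response. Relative to the P4 arm, proliferation genes were higher in the 17-OHPC/P4 arm (camera adjusted p = 8.82e-06, median difference 0.60) and T and NK cell markers lower (6.21e-05, -0.65). Immediate early genes were lower (8.8e-05, -2.05), ciliated cell markers lower (0.0221, -0.36) and unfolded protein response genes higher (0.0375, 0.13, and 0.0638 with the animal as a block). With an estimated correlation each had an adjusted p = 0.878. Only the T and NK difference held without any 1 library. That list was already higher in the 17-OHPC/P4 arm on control day 7 and was not called between arms on treated day 7. The proliferation and immediate early differences were lost as given above. The ciliated difference was lost without the control library of animal B (0.759), D (0.239) or E (0.795) or the treated library of animal A (0.846), C (0.05) or D (0.736). The unfolded protein response difference was lost without the control library of animal A (0.0781), C (0.3), D (0.0863) or F (0.0581) or the treated library of animal A (0.846) or B (0.104), and turned without animal D's treated library (0.649).

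In the untreated day change, 6 lists differed between the arms. Unfolded protein response genes were lower in the 17-OHPC/P4 arm (camera adjusted p = 6.94e-10). T and NK (1.32e-07), proliferation (2.34e-05), endothelial (0.00173) and WNT, hedgehog and BMP lists (0.00424) were higher and the ciliated list lower (0.00996). The ciliated difference rests on animal F (2.38 log2, the only rise), and endothelial means ran from -2.46 (F) to 2.64 (B). With the block the matrix list differed too (0.000595, against 0.153). With an estimated correlation and no block each had an adjusted p = 0.994.

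Progesterone receptor target genes moved in opposite directions in every animal of the arms on treatment, lower in A to C and higher in D to F, with a difference of -0.41 in the mean log2 change. Camera on the response difference did not call this list (adjusted p = 0.151). MSTN (myostatin) rose from day 4 to 7 in A to C (mean 17.1 to 29.3 CPM). It fell in D to F (193 to 29.3), so the gap lay on day 4. The 3.50 log2 difference did not pass edgeR (adjusted p = 0.707).

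The first pattern weighed is the smaller number of genes called between day 4 and day 7 in the 17-OHPC/P4 arm, 8 against 1698 in the P4 arm. It was 108 against 2975 with the animal block, so ignoring the pairing is not its whole cause. Exchanged day 4 and day 7 libraries are excluded, since on genes chosen in the P4 arm the lowest day 7 score of the 17-OHPC/P4 arm lay 0.69 above its highest day 4 score. SEs shared 1 dispersion per gene across all groups and cannot test a larger spread between its animals. That (median SD within control groups 1.19 times the P4 arm's) and a smaller change stay open. The SD of log2 changes across genes was 0.715 times that of the P4 arm, yet 0 genes passed the edgeR test of the difference. Differences between the cows of the arms were not tested.

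The next pattern is the lower level of macrophage and inflammatory genes in the treated cycle. A lower share of every kind of leukocyte stays open in the 17-OHPC/P4 arm (T and NK mean -0.21 ± 0.121, macrophage -0.88 ± 1.05, SD, n = 3). The P4 arm's means (0.35 ± 0.103, -1.13 ± 0.309) argue against it, but 3 animals cannot exclude it. Less blood in the treated brushes stays open in both arms. In the P4 arm the red blood cell list had a mean of 0.0729 ± 0.557, with 0.14, -0.52 and 0.59 in animals D, E and F. It fell only in E, the macrophage list in all 3, and so few animals cannot exclude less blood. In the 17-OHPC/P4 arm its mean was -0.64 ± 1.37. Cycle order (treated second in 6 of 6 animals) and brushing on day 4 (control cycle only) cannot be told apart from treatment. A progestin effect may account for the pattern, but no value parts it from these.

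The last pattern is ENSBTAG00000071406, lower in the 17-OHPC/P4 arm on treated day 7. The treatments are excluded as its whole cause, since the arms already differed by -2.99 log2 on control day 7 and the response difference was -0.31 (95% interval -1.31 to 0.69). A variant or another lasting difference between the cows was not tested and stays open. For ENSBTAG00000072338, the other gene called there, the response difference was -0.61 (95% interval -1.14 to -0.07, adjusted p = 1), and the treatments are not excluded.

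Other splits of the same samples were fitted for every comparison. For day 7 against day 4 in both arms, 2 of 100 splits called as many genes, the real one (2073) and another with 2306, so chance is excluded at a share of 0.05. That other split exchanged animal A's day 4 with animal C's day 7 library. Of all 32 splits that exchange days within animals, which keeps the pairing, only the real one called as many (a share of 0.0312), and the next highest called 208, with animal C exchanged. For treated against control day 7 in both arms, where no gene was called, 56 of 100 splits had as many genes at unadjusted p under 0.05 (real 850, highest other 4039), so chance is not excluded. Several times more genes in other splits point to a structure of the samples. Among all 32 splits that exchange cycles within animals, 10 were as large (highest other 2915), and since every animal then stands on both sides, differences between animals alone do not account for these. Comparisons within or between arms have only 10 splits, too few for a share under 0.05. Within the 17-OHPC/P4 and the P4 arm, the real split and the highest other called 8 and 0, and 1698 and 0 (day 7 against day 4, 1 split as large each), and 134 and 0, and 1468 and 0 (treated day 7 against day 4, 1 each). For treated against control day 7 they had 371 and 2745, and 596 and 3347, genes at unadjusted p under 0.05 (7 splits as large each). Between arms they were 2 and 1 on treated day 7 (1 split), 1 and 1 on control day 7 (2 splits), and 247 and 1537 at unadjusted p under 0.05 for the response difference (6 splits).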

How the results depend on the processing

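Leaving out animal C and the comparison of the day change between arms were chosen after seeing the data. For each value that moved, the cause was not tested. Fits of the compared groups alone, without animal C or without 1 library rest on fewer samples by construction. Counts of called genes for day 7 against day 4 in both arms were 3272 with the replicate block, 3478 with DESeq2 and 1108 with glmTreat against a fold of 1.2, and 945 to 3192 with 1 library left out. In the 17-OHPC/P4 arm they were 108 with the block, 375 with DESeq2, 3 with limma voom, 13 with upper-quartile factors, 28 with the leukocyte covariate, 0 with only the compared groups, 0 without animal C, and 1 to 136 with 1 library left out. For the P4 arm they were 2975 with the block, 3356 with DESeq2, 1030 with glmTreat, and 271 to 2301. For treated against control day 7, DESeq2 called 1 gene in the 17-OHPC/P4 arm, 2 in the P4 arm and 2 in both. For treated day 7 against day 4 in the 17-OHPC/P4 arm the counts were 1029 with the block, 1448 with DESeq2, 210 with upper-quartile factors, 274 with the CPM filter, 0 with only the compared groups, 69 with glmTreat, 5 without animal C, and 3 to 1018. The counts of the P4 arm were 2702 with the block, 2915 with DESeq2, 852 with glmTreat, and 56 to 1455. Between arms on treated day 7 they were 179 with DESeq2, 0 with only the compared groups, 1 without animal C, and 0 to 2. On control day 7 they were 336 with DESeq2, 8 with the CPM filter, 0 with only the compared groups, 2 with the leukocyte covariate, 0 without animal C, and 0 to 264. Other scalings moved the median of all genes by at most -0.0848 log2.

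Of 92 list calls 1 held with an estimated correlation and 12 with fry, which called 16 lists in all, those not called by camera included. Camera with the block kept 77 and lost 6, and with the CPM filter it kept 85 and lost 7. It was not run with the block between arms on treated or control day 7, where no animal stands in both groups. RLE factors kept 92. With 1 library left out 580 list calls kept their side, 134 did not and 6 turned. The interferon list for day 7 against day 4 in the 17-OHPC/P4 arm ranged from adjusted p = 0.000182 to 0.595, where it turned without animal A's control day 7 library. For treated against control day 7 in that arm, without animal C's control library, the immediate early list (6.71e-09 to 0.231) and the matrix list (1.15e-06 to 0.243, and 0.231 where it turned) changed direction. Without the same library the immediate early (1.52e-06 to 0.837) and cholesterol lists (7.72e-06 to 0.936) turned between arms on control day 7. The unfolded protein response in the response difference (5.27e-06 to 0.846) turned without animal D's treated library (0.649). The correlation of the treatment responses was -0.108 without animal F and up to 0.457. The medians of the other arm's genes were 0.46 with the replicate block (0.33 without it) and 0.12 to 0.62 with 1 library left out for the higher genes in the 17-OHPC/P4 arm. They were -0.27 to 0.0348 for the lower genes, and -0.25 to 0.23 and -0.20 to 0.0385 in the P4 arm.

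No named gene turned where it was called. With 1 library left out 1185 gene results kept their side and 591 lost their call. The replicate block ended 8 gene calls, among them PAQR8 (0.0552), CRYGS (0.0573), ZFP36 (0.0517) and CRNN (0.0621) for day 7 against day 4 in both arms, CRNN in the P4 arm (0.0767), and NR4A1 (0.165) and NR4A2 (0.0748) for treated day 7 against day 4 in the P4 arm. It added SLC2A1 (0.0491) in both arms and ESR1 (0.042) in the last comparison. Of the lists it added ciliated markers, lower for treated against control day 7 in the 17-OHPC/P4 arm (0.0325, against 0.0956, and adjusted p = 0.845 with an estimated correlation and no block). Apart from these and those given beside the results, it changed no other call of a gene or list named in the text. Depth limits genes of low level such as NR1I3, at 0.15 CPM on control day 7 of the P4 arm, and CL46, at 0.0666 CPM on day 4.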

Other observations

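The ribosome list, its tests and the tests of list means within animals were chosen after seeing the data. NOP2, RRP8, TSR1, NOLC1, NOL6 and FBL, all factors of ribosome assembly, fell between day 4 and day 7 and prompted a list of 39 ribosome biogenesis genes. Of these, 26 fell and 0 rose in both arms together, with a median log2 change of -0.51 and negative values in 38. Without the 6 prompting genes, 20 of 33 fell, the median was -0.46, and camera with an estimated correlation, from limma, gave p = 0.00356. The same test with an estimated correlation and without the prompting genes gave p = 0.00186 in the 17-OHPC/P4 arm, where 0 genes of the list were called, and p = 0.0158 in the P4 arm. These p values are for a single list and not adjusted. A hypothesis is that ribosome production may fall as a group in the early luteal endometrium, found and tested on the same data. With all 39 genes and an estimated correlation, treated against control day 7 gave p = 0.52 (median 0.08, positive in 23), and the difference of the day change between arms p = 0.678.

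Averaged within animals, 8 of 31 lists were higher on day 7 than on day 4 in 6 of 6 animals and 0 were lower in all of them. Early luteal genes rose by a mean of 1.42 ± 0.467 log2 (SD, n = 6), fatty acid genes by 1.04 ± 0.305 and cholesterol genes by 0.47 ± 0.121, at an exact permutation p = 0.0312, the smallest the design allows, and 0.121 adjusted over the lists.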
